A study of Rattus norvegicus with 18 samples.

How the data were processed

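DNA methylation was measured by reduced representation bisulfite sequencing, in which genomic DNA is cut with MspI at CCGG sites, treated with bisulfite so that unmethylated cytosines read as thymine, and sequenced. The DNA came from left hippocampi of 18 adult male Sprague-Dawley rats, per the labels' protocols. In the seizure rats they were taken 24 hours after the last seizure. The rats fell into 4 groups, given by the labels: 4 sham rats and 4 seizure rats of the intrahippocampal electrical kindling model, and 7 sham rats and 3 seizure rats of the systemic kainic acid model. The seizure groups carry the label of 3 class V seizures. The label set gives each sample as a separate animal. What the sham rats underwent in each model is not given in the sources used here.

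The deposited table holds, per the labels and the values themselves, a methylation fraction (beta value, from 0 to 1) for each cytosine of a CpG in each rat, with each strand on its own row. The submitters' processing notes name FastQC, Trim Galore, Bismark, Bowtie2 and methylKit and the rat build rn6, without versions or the role of each. The minimum coverage and any other filter on cytosines are not given in the sources used here. The table holds 2330883 cytosines with 0 missing values over the 18 rats. It holds fractions and no read counts, so the depth behind each value is unknown, no interval for a single value is given, and tests that need read counts were not run. A methylation fraction that rests on few reads takes coarse steps, and both strands of a CpG then differ more. The SD of that difference between strands, over 1006538 CpGs measured on both, was 4.85 to 6.46 points per rat. The columns were matched to the rats by the library names in the labels, and 0 columns were left unused.

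Levels were multiplied to percent, and differences are given in percentage points as seizure minus sham. The mean level of each rat over all cytosines was compared within each model by a two-sided exact permutation test. With 4 against 4 rats there are 70 arrangements and the smallest p is 0.0286. With 7 against 3 rats there are 120 arrangements and the smallest p is 0.0167. For regional differences, cytosines were averaged in non-overlapping tiles of 1000 bp holding at least 3 measured cytosines. Of 151450 such tiles, the 84584 whose range over the 18 rats was at least 5 points were tested. Single cytosines were tested where the range was at least 10 points, which left 794376, or 34.1% of the table. The tests used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), on the fraction scale, with 1 fit over all 4 groups, 14 residual degrees of freedom and a variance prior that follows the mean level. The contrasts were seizure minus sham in each model, the mean of both, the kainic acid difference minus the kindling difference, and kainic acid sham minus kindling sham. A tile or cytosine was called at a Benjamini-Hochberg adjusted p under 0.05 over all units of that contrast. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

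The fit was tested on simulated data with the means and spreads of the real tiles and cytosines and 50 units changed at each size. For tiles of intermediate level, a difference of 10 points was called in 26% of cases in the kindling comparison and 26% in the kainic acid comparison. A difference of 20 points was called in 78% and 72%, and a difference of 30 points in 100% and 96%. For single cytosines, also of intermediate level, a difference of 30 points was called in 44% of cases in kindling and 40% in kainic acid. A difference of 20 points was called in 4% and 2%. Changes at low or high levels were not simulated. Among the unchanged units of these simulations, 5 tiles and 0 cytosines were called for kindling and 8 tiles and 7 cytosines for kainic acid. In 20 further simulations with no changed unit, added after seeing the data, 0 to 2 tiles and 0 to 1 cytosines were called for kindling and 0 to 1 tiles and 0 to 2 cytosines for kainic acid. These draws take the units as independent with a normal spread, which the data need not follow.

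The tests, the contrasts, the settings tried and the rule for the tiles named were chosen before the data were examined. The rule names, for each of 4 contrasts, the 10 called tiles with the largest gain and the 10 with the largest loss, or, where under 5 pass, the 5 with the smallest p in each direction, given as values and not as calls. The rule left single cytosines out. The called cytosines are named because they are few, and that choice was made after their values were seen, as was the contrast between models at single cytosines. Alternatives covered the tile length, the number of cytosines, the range filters, the log2 odds scale (M values, with levels held between 1 and 99%), the replicate number as a block, fits within 1 model, the mean level as a covariate, limma array weights, other thresholds, and leaving out each rat in turn. Averaged strands, autosomes only, a robust prior, the share of values of exactly 0 as a covariate and a fit without 4 low-weight libraries were added after seeing the data.

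No gene annotation of rn6 was used here, since the gene table at hand is for another assembly (GRCr8) and coordinates were not converted between builds. The planned promoter tests and the tests of 16 gene lists were therefore not run, and regions are named by their rn6 coordinates alone, without the gene, exon or intron they lie in.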

Results

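Methylation of hippocampal DNA was compared between sham rats and rats with 3 class V seizures, the generalised convulsive stage of the behavioural seizure scale, in 2 models of temporal lobe epilepsy. In kindling, brief electrical stimulation of the hippocampus is repeated until seizures generalise. In the kainic acid model, systemic injections of this glutamate receptor agonist induce status epilepticus. The kindling groups held 4 sham and 4 seizure rats and the kainic acid groups 7 sham and 3 seizure rats. The title of the series names the question, which is what the models share in their methylation changes.

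The 2330883 cytosines had the bimodal levels of a CpG-rich fraction of the genome. Of these, 48.1% had a mean level under 10%, 23.4% between 10 and 90%, and 28.6% above 90%. The table covered 39034 cytosines on the X chromosome, with a mean level of 42.9% ± 0.387 (SD, n = 4) in kindling sham rats, and 9460 on the Y chromosome, with 86.0% ± 0.240 (SD, n = 4). Pearson's r between rats, across a regularly spaced subset of the cytosines, ran from 0.986 to 0.993 (cytosines are not independent replicates). With such bimodal levels r is high for nearly any pair of rats, so it does not show that the libraries were alike. The depth of each library is unknown. The share of values of exactly 0, which can rise when fewer reads lie over a cytosine, ranged from 8.89% in kindling seizure rat 1 to 25.4% in kindling sham rat 4. Its mean was 17.6% ± 6.39 (SD, n = 4) in kindling sham rats, 13.4% ± 5.31 (SD, n = 4) in kindling seizure rats, 13.8% ± 3.63 (SD, n = 7) in kainic acid sham rats and 10.2% ± 1.91 (SD, n = 3) in kainic acid seizure rats. These shares did not differ between sham and seizure rats beyond the spread (exact permutation p = 0.343 in kindling and 0.117 in kainic acid).

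Genome-wide methylation of the hippocampus was nearly the same with and without seizures. In kindling the mean level was 42.5% ± 0.384 (SD, n = 4) in sham rats and 42.7% ± 0.469 (SD, n = 4) in seizure rats, a difference of 0.267 points (two-sided exact permutation p = 0.4). With single rats left out that difference ran from 0.0966 points (without seizure rat 3) to 0.412 points (without seizure rat 4). It also moved by over 1.5 times without seizure rat 1 (0.173), sham rat 1 (0.402) or sham rat 2 (0.133). It passed in none of these (exact permutation p at least 0.229). In kainic acid it was 42.5% ± 0.280 (SD, n = 7) in sham rats and 42.8% ± 0.0892 (SD, n = 3) in seizure rats, a difference of 0.331 points (two-sided exact permutation p = 0.1). Without kainic acid sham rat 6 that difference was 0.396 points and passed the threshold (exact permutation p = 0.0476). The mean was higher in seizure rats on each of 21 chromosomes (autosomes and X) in both models, by 0.187 to 0.319 points in kindling and by 0.288 to 0.365 points in kainic acid, and no chromosome passed the test (smallest adjusted exact permutation p = 0.474 and 0.258).

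Of these small differences, the largest by value lay in cytosines of intermediate level. Their lead over cytosines under 10% was 0.211 points in kindling (exact permutation p = 0.629) and 0.0194 points in kainic acid, within the spread between rats. Cytosines with a mean between 10 and 90% had 59.95% ± 0.615 (SD, n = 4) in kindling sham rats and 60.4% ± 0.373 (SD, n = 4) in kindling seizure rats, a difference of 0.477 points (adjusted exact permutation p = 0.714). The kainic acid difference for this class was 0.474 points (adjusted exact permutation p = 0.444). Cytosines under 10% differed by 0.266 points in kindling and 0.455 points in kainic acid, and those above 90% by 0.0980 and 0.00395 points. On the Y chromosome the differences were -0.0475 and 0.143 points. The class under 10% ran from 1.16 to 2.38% in kindling sham rats and from 1.23 to 2.88% in kindling seizure rats. Single rats can therefore move these small class differences, and fits of the classes with rats left out were not made. None of the 10 comparisons of classes and sex chromosomes passed the test (all adjusted exact permutation p at least 0.444).

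**Figure D1:**
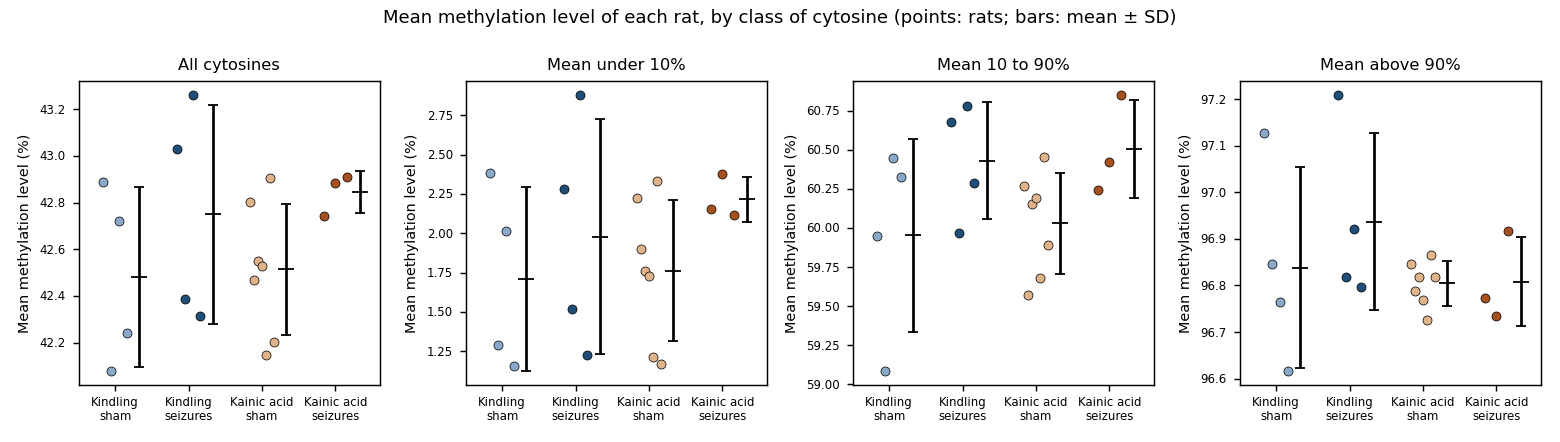
Mean methylation level in percent of each rat over all cytosines and over cytosines with a mean under 10%, from 10 to 90% and above 90%, by group (points are rats, bars the mean and SD; each axis covers only the range of the values). The groups overlap in every panel, and kainic acid seizure rats lie between 42.7 and 42.9% over all cytosines against 42.1 to 42.9% in kainic acid sham rats.

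The kindling comparison asked which regions of the hippocampal genome differ in methylation after repeated stimulation. No region of 1000 bp passed the test among 84584. The 5 tiles with the smallest p in each direction differed by 6.07 to 22.9 points in size. In 9 of these 10 the values of the 4 seizure rats did not overlap those of the 4 sham rats, which chance gives for a share of 0.0286 of tiles, and these were picked for a small p. A tile on chromosome 1 (start 226245001, end 226246000, 18 cytosines) had 44.3% ± 2.58 (SD, n = 4) in sham rats and 54.8% ± 1.34 (SD, n = 4) in seizure rats. Another on chromosome 1 (start 218478001, end 218479000) had 53.6% ± 9.29 (SD, n = 4) against 73.7% ± 5.25 (SD, n = 4). On chromosome 15 (start 17891001, end 17892000) the sham rats had 71.9% ± 5.81 (SD, n = 4) and the seizure rats 48.9% ± 4.09 (SD, n = 4). On chromosome 2 (start 258583001, end 258584000) the levels were 87.3% ± 5.80 (SD, n = 4) and 71.9% ± 4.12 (SD, n = 4).

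At several of these kindling tiles the seizure rats had a level near that of the kainic acid rats. The chromosome 1 tile starting at 226245001 had 54.7% ± 2.82 (SD, n = 7) in kainic acid sham rats and 52.7% ± 1.41 (SD, n = 3) in kainic acid seizure rats. The chromosome 15 tile had 51.8% ± 10.1 (SD, n = 7) and 52.9% ± 0.904 (SD, n = 3). A tile on chromosome 19 (start 23138001, end 23139000) had 48.7% ± 2.71 (SD, n = 4) in kindling sham rats, 59.4% ± 1.78 (SD, n = 4) in kindling seizure rats, 59.7% ± 2.79 (SD, n = 7) in kainic acid sham rats and 62.3% ± 2.54 (SD, n = 3) in kainic acid seizure rats. Among the 100 tiles with the smallest kindling p, the kainic acid sham mean was closer to the kindling seizure mean than to the kindling sham mean in 70, a number reached by 5 of 70 arrangements of the kindling rats (median of the others 50). Tiles going the other way included the chromosome 2 tile, with 83.0% in kainic acid sham rats, and one on chromosome 3 (start 162828001), with 92.0% in kainic acid sham rats against 93.8% and 87.7% in kindling sham and seizure rats.

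By limma, 0 tiles passed an adjusted p of 0.05 (smallest 0.682) and 4829 tiles, 5.71%, had an unadjusted p under 0.05, of which 3034 were higher and 1795 lower in seizure rats. The median 95% interval of a tile difference reached 4.03 points to either side. Among single cytosines 0 of 794376 passed (smallest limma adjusted p 0.145) and 45471 had an unadjusted p under 0.05. The outcome depended on kindling sham rat 1: without it, 9 tiles and 52 cytosines passed, and at all 9 tiles the level of that rat was closer to the seizure rats than to the other sham rats, as tiles that pass only without a rat tend to show. Without kindling sham rat 2, 1 tile and 20 cytosines passed, and without sham rat 4, 7 cytosines. Leaving out a seizure rat gave 1 cytosine (rat 1), 1 tile and 2 cytosines (rat 2), 1 tile and 3 cytosines (rat 3), and 1 tile and 5 cytosines (rat 4). Most of the 9 tiles lay on chromosome 20, with starts from 11447001 to 12311001 and at 47655001 and 47832001. The tile starting at 47832001 (end 47833000) had 53.9% ± 1.82 (SD, n = 3) in kindling sham rats 2 to 4 and 74.5% in sham rat 1. It had 75.9% ± 0.700 (SD, n = 4) in seizure rats, and means of 75.8% and 75.6% in kainic acid sham and seizure rats. At cytosines with a range above 60 points, kindling sham rat 1 also had the largest share of levels between 15 and 35% or between 65 and 85%. That share was 38.7%, against 23.2 to 29.3% in the other 17 rats. Levels between 35 and 65% were not counted.

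The kainic acid comparison asked the same of chemically induced seizures. By limma, methylation differed at 5 single cytosines, a number that 16 of 100 splits of these rats, the real one included, also reached. They lie at 3 places on chromosomes 9 and 16. On chromosome 9, the cytosine at 16510571 (plus strand) rose from 0.431% ± 0.449 (SD, n = 7) in sham rats to 50.1% ± 6.79 (SD, n = 3) in seizure rats (limma adjusted p = 0.000103). Its partner on the minus strand, 16510572, rose from 0.550% ± 0.978 (SD, n = 7) to 40.3% ± 3.29 (SD, n = 3) (limma adjusted p = 0.00373). On chromosome 16, the plus-strand cytosine at 20849982 fell from 96.8% ± 2.61 (SD, n = 7) to 47.1% ± 4.43 (SD, n = 3) and the minus-strand cytosine at 20849983 fell from 97.0% ± 1.35 (SD, n = 7) to 49.1% ± 7.56 (SD, n = 3), with limma adjusted p of 0.0340 and 0.00373. The plus-strand cytosine at 20988231 on chromosome 16 fell from 88.3% ± 5.66 (SD, n = 7) to 45.0% ± 4.02 (SD, n = 3) (limma adjusted p = 0.00373).

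Few neighbouring cytosines differed with them. Of 27 other cytosines within 500 bp of each called chromosome 9 cytosine, 1 differed by over 10 points in the same direction, and it was the partner on the other strand. Around 20849982 that was 1 of 3 cytosines, again the partner, and around 20988231 it was 1 of 20, at another CpG, with the opposite strand not measured. Levels between 20 and 80% also occurred in rats without seizures. Of the 11 sham rats, 2 lay inside the range of the kainic acid seizure rats at 20849982 and 1 at 20988231. At 20849983, 16510571 and 16510572 that number was 0. At 20988231 all 4 kindling sham rats lay between 20 and 80% (45.0 to 73.3%), at 20849982 and 20849983 3 of the 4 did, and on chromosome 9 kindling sham rat 1 had 27.5% and 29.9% where the other 3 had at most 3.13%. Rats of the kindling seizure group had 89.1 to 98.6% at 20849982 and 93.6 to 100% at 20988231.

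**Figure D2:**
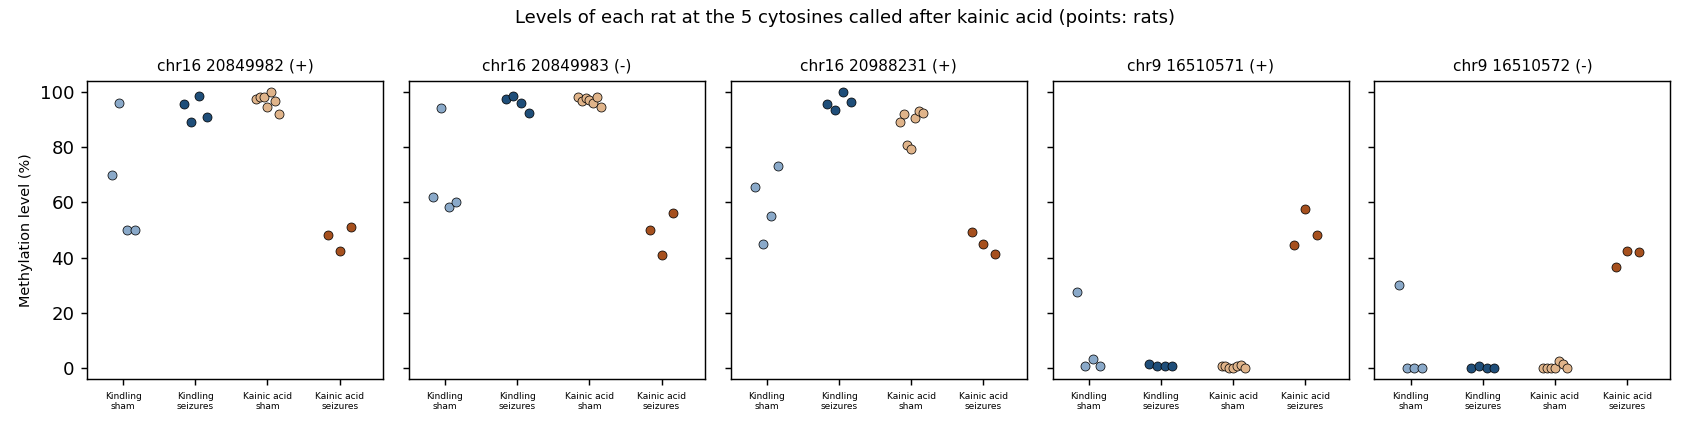
Methylation level in percent of each rat (points) in the 4 groups at the 5 cytosines called in the kainic acid comparison, named by chromosome, rn6 position and strand. The 3 kainic acid seizure rats lie between 36.5 and 57.7% at each. Kindling sham rats lie between 45.0 and 73.3% at 20988231 on chromosome 16, where 1 sham rat is inside the range of the seizure rats.

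None of the 84584 tiles passed in kainic acid. Of the 100 tiles with the smallest p, 7 lay between 15 and 17 Mb on chromosome 9, where 170 of all tiles were tested. The tile nearest to the threshold lay on chromosome 13 (start 51084001, end 51085000, 4 cytosines), with 71.4% ± 2.68 (SD, n = 7) in sham rats and 57.3% ± 1.97 (SD, n = 3) in seizure rats (limma adjusted p = 0.179), and it passed narrowly with array weights (limma adjusted p = 0.0499955). A tile on chromosome 2 (start 30017001, end 30018000, 8 cytosines) had 67.2% ± 1.49 (SD, n = 7) against 82.4% ± 4.96 (SD, n = 3), and one on chromosome 5 (start 152526001, end 152527000) had 90.6% ± 4.48 (SD, n = 7) against 69.5% ± 8.26 (SD, n = 3). Among the 5 tiles of smallest p in each direction were a pair on the X chromosome with small differences, of 4.23 points (start 124894001, end 124895000) and -3.79 points (start 134448001, end 134449000), where all 7 sham rats had 0% and 100%. A tile on chromosome 9 starting at 16655001 (end 16656000) had 91.0% ± 2.03 (SD, n = 7) against 81.7% ± 4.53 (SD, n = 3).

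By limma, 0 tiles passed (smallest adjusted p 0.179) and 2997 tiles, 3.54%, had an unadjusted p under 0.05, of which 1805 were higher and 1192 lower in seizure rats. The median 95% interval of a tile difference reached 3.94 points to either side. Among cytosines 5 passed and 30372 had an unadjusted p under 0.05. The same fit called 7 unchanged cytosines in simulated data that also held changed ones, and 0 to 2 in 20 simulations without change, which take cytosines as independent and normally spread. On the log2 odds scale 0 cytosines passed, and without kainic acid seizure rats 1 or 2, which leaves 2 rats in that group, 28 and 54 cytosines and 5 and 3 tiles passed, 4 cytosines being shared with the 5 each time. Without kainic acid seizure rat 3, 4 cytosines passed, of which 2 were among the 5. Without kainic acid sham rat 4, 1 tile passed, and 8 cytosines passed without kindling sham rat 1, 2 or 4 or kindling seizure rat 3.

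**Figure D3:**
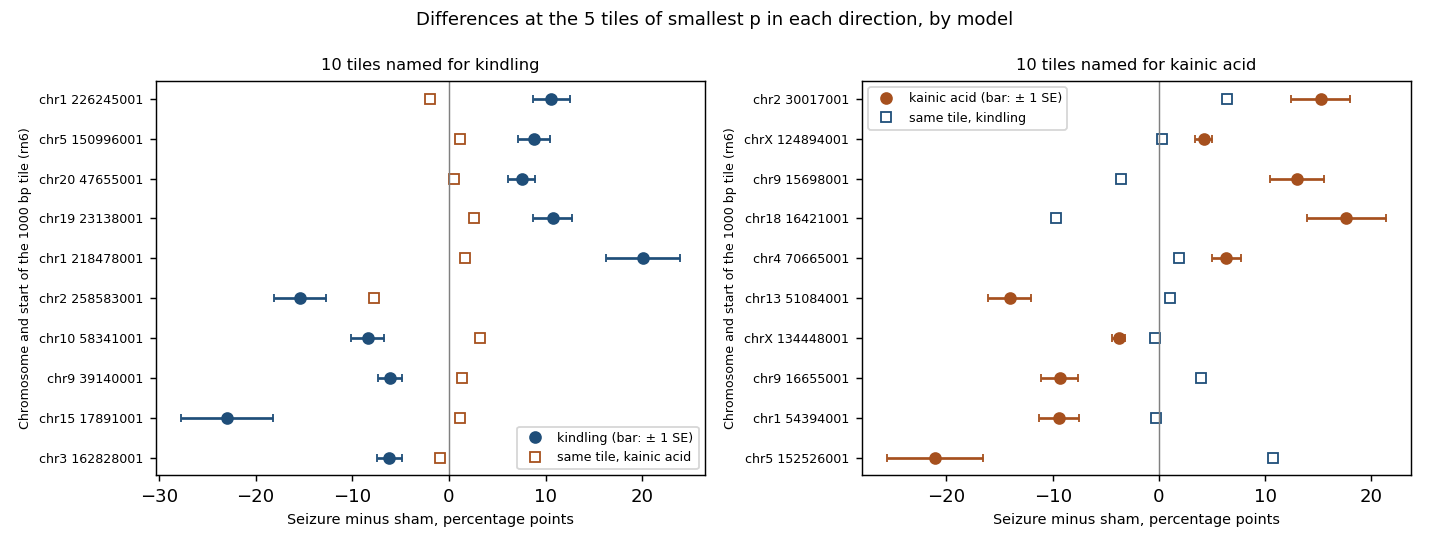
Difference in methylation (seizure minus sham, percentage points) at the 5 tiles with the smallest p in each direction in kindling and in kainic acid, named by chromosome and start; filled points with bars are the fitted difference and its SE in the model that named the tile, open squares the difference in the other model. For kindling tiles the differences range from -22.9 to 20.1 points. The open squares lie nearer to 0 than the filled points at each of the 10 kindling tiles and at each kainic acid tile. Tiles picked for a small p in 1 model tend to show this, so it does not mark a change as particular to a model.

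Changes shared by both models were sought next, since the series asks for commonalities. No tile passed for the mean of both differences. The tile nearest to the threshold was the chromosome 2 tile starting at 258583001, with differences of -15.4 points in kindling and -7.71 points in kainic acid (limma adjusted p of the mean 0.773). The largest differences among the 5 tiles of smallest p in each direction lay on chromosome 12 (start 23659001, end 23660000, 11 cytosines), with 96.3% ± 1.51 (SD, n = 4) and 74.5% ± 6.51 (SD, n = 4) in kindling sham and seizure rats and 81.4% ± 11.3 (SD, n = 7) and 52.5% ± 23.01 (SD, n = 3) in kainic acid sham and seizure rats. Kainic acid seizure rat 2 had 26.0% there, and without it the kainic acid difference was -15.6 points instead of -28.9. On chromosome 10 (start 44431001, end 44432000) the differences were -15.7 points in kindling and -16.7 points in kainic acid, and on chromosome 9 (start 15608001, end 15609000, 20 cytosines) they were 5.35 and 6.11 points (3.92 in kainic acid without seizure rat 2). At the chromosome 10 tile kainic acid sham rat 2 had 51.6%, inside the 46.9 to 51.9% of the kainic acid seizure rats.

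By limma, 0 tiles passed (smallest adjusted p 0.773) and 3854 had an unadjusted p under 0.05, of which 2599 were higher and 1255 lower after seizures. Across the 84584 tiles, which are not independent replicates, the differences of the models had a Pearson's r of -0.0546 (permutation p = 0.495, 100 relabellings of the rats within each model, whose r ran from -0.293 to 0.334) and a Spearman's rho of -0.00552 (permutation p = 0.970). The sign of r turned without kindling sham rat 1 (0.0118) and without kindling seizure rat 4 (0.0298). Tiles with an unadjusted p under 0.05 in both models numbered 109 in the same direction and 184 in opposite directions, against 90.04 and 81.06 for independent lists and medians of 140.5 and 134 in the relabellings (permutation p = 0.822 and 0.208). Without kindling sham rat 1, 4 tiles passed for the mean of both differences, and without kainic acid seizure rat 2, 2 tiles.

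The difference between models passed at the same 5 cytosines that were called in kainic acid, and it includes the kainic acid difference. The kainic acid difference minus the kindling difference was 56.8 points at 16510571 and 47.1 points at 16510572 on chromosome 9 (limma adjusted p = 0.00160 and 0.0450), and -76.8, -75.4 and -79.9 points at 20849982, 20849983 and 20988231 on chromosome 16 (limma adjusted p = 0.0133, 0.00160 and 0.000139). At the chromosome 16 cytosines the kindling seizure rats were higher than their sham rats, by 27.1, 27.4 and 36.7 points, and these kindling differences did not pass (smallest limma adjusted p 0.145). No tile passed for the difference between models (limma, smallest adjusted p 0.499), and 4021 tiles had an unadjusted p under 0.05. The tile with the largest such difference among the 5 of smallest p in each direction lay on chromosome 20 (start 13154001, end 13155000), with 64.9% ± 6.90 (SD, n = 4) in kindling sham rats, 86.3% ± 0.453 (SD, n = 4) in kindling seizure rats, 80.2% ± 8.79 (SD, n = 7) in kainic acid sham rats and 65.8% ± 8.36 (SD, n = 3) in kainic acid seizure rats. A tile on chromosome 15 (start 35004001, end 35005000) had differences of -13.2 points in kindling and 19.9 points in kainic acid. Without kindling sham rat 1, 7 tiles passed, without kainic acid seizure rat 1 or 2, 2 and 3 tiles, and without kainic acid sham rat 4, 1 tile.

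The sham groups of the models were compared as a measure of how far rats without seizures differ between the arms of the study. No tile passed (limma, smallest adjusted p 0.207). Of the contrasts tested, this one had the most tiles with an unadjusted p under 0.05, at 5370 or 6.35%, of which 2775 were higher and 2595 lower in kainic acid sham rats. Without kindling sham rat 1, 13 tiles passed, and without kindling sham rat 2 or 3, 4 tiles each.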

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

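The test of whether rats of a group are more alike at variable cytosines and the count of splits that call as many cytosines were fixed before their results were seen, and the other tests weighed below were chosen after the results were seen. At the 5 cytosines called in kainic acid the difference between models also passed. The kainic acid difference minus the kindling difference was -76.8, -75.4 and -79.9 points at 20849982, 20849983 and 20988231 on chromosome 16, and 56.8 and 47.1 points at 16510571 and 16510572 on chromosome 9. This contrast includes the kainic acid difference that picked these cytosines. The kindling difference alone passed at none of them (limma adjusted p at least 0.145), and on chromosome 9 it was -7.18 and -7.35 points. At 20849982 the sham rats already differed, with means of 66.5% in kindling and 96.8% in kainic acid.

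Measurement error confined to 1 strand is argued against at 2 CpGs, 1 on chromosome 16 and 1 on chromosome 9. There both strands differed by at least 20 points in the same direction, though both strands were also picked for their difference. Errors that affect both strands alike are not covered, and at 20988231 the opposite strand was not measured. Sequence variants or haplotypes that differ between rats could account for these sites and stay open: all 3 seizure rats lay between 35 and 65% and at least 1 sham rat between 20 and 80% at 3 of 3 cytosines on chromosome 16 and at 2 of 2 on chromosome 9, but this restates levels seen before the window was set and decides nothing, and on chromosome 9 the only such sham rat was kindling sham rat 1. The 100 tiles with the smallest kainic acid p held 50 pairs lying 10 kb to 2 Mb apart. In 1000 random draws of tiles the highest value was 32. Of 99 other splits of the kainic acid rats, 8 held at least 50 (median 20). Such splits can keep 2 of the 3 seizure rats together, so whether the clustering is particular to the seizure rats stays undecided. At the 12712 cytosines with a range above 60 points, the mean correlation was -0.0261 within groups and -0.0679 between groups (one-sided permutation p = 0.0447). Within groups it was positive only among kainic acid seizure rats, at 0.111 over 3 pairs (from -0.0988 to 0.426). In the other groups it was -0.0529 to -0.0341. As 0 of the 5 called cytosines are in that set, this decides nothing for them. An effect of seizures after kainic acid stays open, since at least 1 sham rat lay inside the range of the seizure rats at 2 of 3 cytosines on chromosome 16 and at 0 of 2 on chromosome 9, and chance is not excluded for the number of calls, as 16 of 100 splits of the kainic acid rats called at least 5 cytosines (highest other split 27).

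Kindling sham rat 1 lay far from the other 3 rats of its group at 4 values. It had 27.5% and 29.9% at 16510571 and 16510572 on chromosome 9, where the others had 0.538 to 3.13% and 0%. It had 89.9% in the chromosome 20 tile starting at 47655001 (others 81.1 to 82.5%) and 82.8% in the chromosome 9 tile starting at 16655001 (others 88.3 to 89.3%). In the kindling rats, 1 other split called 726 tiles where the real split called 0, and it differs from the real one by exchanging sham rat 1 and seizure rat 4, which points to a structure of these samples other than the labelled groups.

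For sham rat 1, DNA of more than 1 rat in the library is a candidate explanation: at 54 cytosines where kainic acid seizure rats 1 and 3 both deviated from the other rats, it lay 0.25 to 0.75 of the way towards them in 40.7% of cases, against at most 10.6% in each of the other 15 rats, each on its own 33 to 48 such cytosines. Kainic acid sham rat 5 lay near them at 50% of its 48 (median position 0.753), so other rats carry these levels, and haplotypes shared between rats stay open beside a mixture. Kainic acid seizure rat 3 was also the rat most alike to kindling sham rat 1 at cytosines with a range above 60 points (r = 0.285 across cytosines). A larger share for sham rat 1 on this pair can thus be partly built in, and it does not decide for a mixture. The 726 tiles could reflect a difference between libraries. The share of values of exactly 0 was 17.01 to 25.4% in 4 rats on the side of sham rats 2 to 4. It was 8.89 to 13.9% in the other kindling rats. Kindling seizure rat 4 had the lowest array weight of all rats (0.365), and sham rat 1 had 1.05. The 4 libraries of lowest weight were kindling sham rats 3 and 4, kindling seizure rat 4 and kainic acid sham rat 5. They also had the highest shares of exactly 0, of 18.1 to 25.4%. Over the 10 kainic acid rats the position on the 726 tiles fell with that share without passing the test (Pearson's r = -0.625, permutation p = 0.0617, Spearman's rho = -0.539, permutation p = 0.116, and r = -0.140 without the 2 farthest rats). Exchanged labels of sham rat 1 and seizure rat 4 could give the same split. At the 3 called cytosines of chromosome 16, sham rat 1 (70, 62 and 65.5%) and seizure rat 4 (90.9, 92.3 and 96.3%) lay nearer to the mean of their labelled groups. These few sites cannot settle it, since the means include these rats and 2 of the sites are strands of 1 CpG. At 20988231 the kindling p under these labels was also the smallest of all tested cytosines (limma unadjusted p = 2.57e-07). The kainic acid seizure rats did not lie on the side of most kindling seizure rats beyond the spread (mean position 0.528 against 0.379 in sham rats, exact permutation p = 0.25). With 10 rats, a difference between libraries and exchanged labels cannot be told apart. A shift of all kindling sham libraries also stays open, since the kainic acid sham mean was closer to the kindling seizure mean in 70 of the 100 tiles with the smallest kindling p, a number that 5 of 70 arrangements of the kindling rats reached (highest other 83).

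Single rats stood far from their group at 9 other values. Kindling seizure rat 4 had a mean of 85.1% on the Y chromosome (others 86.2 to 86.4%). Kindling sham rat 2 had 94.1% at 20849983 on chromosome 16 (others 58.3 to 62.0%), and kindling seizure rat 2 had 0.524% at 16510572 on chromosome 9 (others 0%). Kainic acid sham rat 4 had 63.9% in the chromosome 2 tile starting at 30017001 (others 67.4 to 68.2%) and 89.5% in the chromosome 18 tile starting at 16421001 (others 64.9 to 72.2%). Kainic acid sham rat 6 had 67.4% in the chromosome 1 tile starting at 169239001 (others 78.2 to 80.5%). Kindling seizure rat 3 had 60.9% in the chromosome 15 tile starting at 35004001 (others 74.3 to 76.7%). On the X chromosome, kindling seizure rat 2 had 1.23% in the tile starting at 124894001 (others 0%) and kindling seizure rat 1 had 98.5% in the tile starting at 134448001 (others 100%). In all, 13 of 135 groups of values held such a rat, and chance alone gives about 6.75, or 1 in 20.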

How the results depend on the processing

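Averaged strands, autosomes only, a robust prior, the share of values of exactly 0 as a covariate and the fit without 4 low-weight libraries were chosen after seeing the data. Depth is unknown and limits how far a single value can be trusted, and the planned tests on read counts, promoters and gene lists were not run. Since the table has no missing values, the settings on missing values changed nothing by construction. The tests of mean level stayed on their side of the threshold with autosomes only and with the median over tiles. With each rat left out in turn the kindling difference ranged from 0.0966 to 0.412 points and never passed, and the kainic acid difference ranged from 0.270 to 0.396 points and passed without sham rat 6.

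Tile counts with each rat left out ranged from 0 to 9 in kindling, 0 to 5 in kainic acid, 0 to 4 for both models together, 0 to 7 for the difference between models and 0 to 13 between sham groups, with the highest count without kindling sham rat 1 except in kainic acid (without seizure rat 1). Without the filter on range 1 tile passed in kainic acid and 1 for both models, and array weights gave 1 in kainic acid. The other settings gave 0 tiles. The correlation between models ranged from -0.0948 to 0.0298 with rats left out, and was 0.0118 without kindling sham rat 1 and 0.0298 without kindling seizure rat 4, both reversed in sign and far from passing. Of 220 comparisons of the 40 named tiles, in which leaving out rats was represented by the smallest difference alone, 219 stayed on their side of the threshold. Over all 720 omissions of 1 rat from these tiles, 5 passed, each in another tile or contrast, 1 of them without kindling sham rat 1 (chromosome 20, start 47655001).

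Cytosine counts moved most. In kindling (0) they ranged from 0 to 52 with rats left out, the highest without sham rat 1, and were 7 without the range filter, 8 within the model alone and 2 without the 4 low-weight libraries. In kainic acid (5) they ranged from 4 to 54 with rats left out, the highest without seizure rat 2, and were 0 on the log2 odds scale, 16 with array weights, 18 within the model alone, 228 without the range filter, 8 without cytosines of a range above 60 points, 14 at an adjusted p under 0.1 and 15 without the 4 low-weight libraries. The 5 were among the 16, the 18 and the 228. Averaging strands gave 6 CpGs in kainic acid. The cause of these moves was not tested.

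The replicate number gave no clear sign of pairing. Deviations of rats with the same number had correlations of -0.111 to 0.155 in kindling (mean 0.0641) and -0.0418 to -0.0156 in kainic acid. For rats with different numbers they were -0.326 to 0.249 (mean -0.0190) and -0.123 to 0.133. With 4 and 3 pairs of the same number, pairing cannot be excluded. With the replicate number as a block, 0 tiles passed in each contrast, 1 cytosine passed in kindling and 34 in kainic acid, 1 of them among the 5. In that fit kainic acid sham rats 4 to 7 have no seizure rat of the same number and do not inform the kainic acid difference. It rests on 3 pairs, so the 34 and the 5 do not rest on the same rats.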

Other observations

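The tests of library background and the counts of other splits were set before their results were seen, except the test of the mean level over both models and the comparison with cytosines of 10 to 90%, which were chosen after. Single cytosines with large kindling differences are given as values, since none passed (limma, smallest adjusted p 0.145). At 150397565 on chromosome 4 (minus strand) the level was 7.27% ± 8.91 (SD, n = 4) in kindling sham rats, 62.0% ± 17.1 (SD, n = 4) in kindling seizure rats, 56.3% ± 10.8 (SD, n = 7) in kainic acid sham rats and 42.3% ± 13.3 (SD, n = 3) in kainic acid seizure rats. At 160875919 on chromosome 3 (plus strand) it was 92.0% ± 5.39 (SD, n = 4), 63.6% ± 4.46 (SD, n = 4), 78.5% ± 5.79 (SD, n = 7) and 85.7% ± 4.23 (SD, n = 3) in the same order.

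When strands were averaged, 3 CpGs passed in kainic acid besides those at the 3 places already described: 97209941 on chromosome 10 (9.57 points, limma adjusted p = 0.0179), 12384782 on chromosome 7 (-25.2 points, 0.0468) and 16660861 on chromosome 9 (24.5 points, 0.0150). At cytosines with a range above 60 points, 7 of 18 rats were most alike to a rat of their own group, and the closest pairs were kindling seizure rats 1 and 2 (r = 0.438 across cytosines) and kainic acid seizure rats 1 and 3 (r = 0.426).

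The median difference over tested tiles was 0.299 points in kindling and 0.311 points in kainic acid. The median tile level of each rat was higher after seizures by 0.355 and 0.286 points (exact permutation p = 0.171 and 0.15). Chance could give these differences. The mean level over all cytosines, another measure, differed by 0.299 points over both models (two-sided exact permutation p = 0.0912 over 8400 arrangements). Background signal at unmethylated CpGs that varies between libraries stays open. Cytosines under 10% differed by more than those above 90% in both models, by at least 0.168 points. Those of 10 to 90% differed by 0.477 and 0.474 points, where such a background would give 0.108 and 0.185 points. The excess over that background was within the spread between rats (exact permutation p = 0.343 and 0.25). The lead of the 10 to 90% class over cytosines under 10% was 0.211 points in kindling (exact permutation p = 0.629) and 0.0194 points in kainic acid.

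Other splits of the same rats were counted for tiles and cytosines. For tiles at an adjusted p under 0.05 the real count was 0 in each contrast, which every split reaches by construction, so these counts say nothing about chance: all 35 splits of the kindling rats and all 100 splits or relabellings drawn for each of the other 4 contrasts were as high, with highest counts of 726, 3, 221, 4 and 8 for kindling, kainic acid, both models, the difference between models and sham groups. At an unadjusted p under 0.05, 18 of 35 splits reached the 4829 tiles of kindling (highest other 15301), 53 of 100 the 2997 of kainic acid (4496), 58 of 100 the 3854 of both models (14210), 42 of 100 the 4021 of the difference between models (11471) and 7 of 100 the 5370 between sham groups (7000). For single cytosines in kindling the same holds of the real count of 0, reached by all 35 splits (highest other 14), and 19 of 35 reached the 45471 at an unadjusted p under 0.05 (92423). In kainic acid 56 of 100 splits reached the 30372 at an unadjusted p under 0.05 (38879). Chance is excluded for none of the counts at an unadjusted p under 0.05.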
